A study of Mus musculus with 12 samples.

How the data were processed

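Single-cell RNA sequencing was deposited for 12 libraries of sorted mouse cells. Per the labels, the libraries were made with 10x Genomics 3' chemistry, version 2, and sequenced on a HiSeq instrument. Every library is labelled Ptch1+/-p53-/-, a model of Sonic hedgehog (SHH) medulloblastoma, with Ccr2-/- added in the knockouts. Tumor tissue came from 8-week-old mice. Cells were enriched on a Percoll gradient and with magnetic beads against CD11 or CD45. The cerebellum and blood libraries, labelled as untreated, were pooled from 3 mice at 2 weeks of age. The deposited matrices hold raw counts of unique molecular identifiers (UMIs), 1 per gene and cell barcode, which the authors made with Cell Ranger on the mouse build mm10. The submitters' notes also name Seurat 3.0, and the matrices hold whole numbers, so no scaling entered them. The matrix headers name version 3.0.0 for the CD11 knockout library and CD45 knockout replicate 1, and version 3.1.0 for the intact CD45 library and CD45 knockout replicate 2. The other 8 libraries carry 27998 genes, these 4 carry 31053, and 27514 shared genes were used throughout.

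The files held 35992 barcodes. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 32971. Scrublet, run in scanpy 1.11.5, marked 21 cells at its automatic threshold, so the highest-scoring cells of each library were removed up to an expected share of 0.8% per 1000 barcodes. This took out 1046 cells and left 31925. The lowest UMI count of any barcode was between 1975 and 2835 in the 8 libraries with the smaller gene set and between 500 and 501 in the other 4, so the minimum that had been applied before deposition differed between these sets, and the files do not show at which step. Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbors and the Leiden method at resolution 1.0 (leidenalg 0.10.2) gave clusters, with no batch correction. Round 1 took all cells, round 2 only microglia, monocytes, macrophages and conventional dendritic cells. Each of the 43 clusters was named from 22 marker lists written before the data were examined, and a name needed at least 3 detected markers, a lead of 0.2 between the microglia, monocyte and border-associated macrophage lists, and no other list with more markers among the 10 leading genes of the cluster. The 2-round scheme, the lead and the lists it applies to, the counting of leading genes by lineage (monocytes with macrophages, and both dendritic cell lists) and the merging of clusters into 14 classes were chosen after looking at the clusters and before any gene was tested. Hence 1 round was added as an alternative. The names end in "-like" because they rest on RNA alone. Cluster 22 missed the lead and clusters 5 and 33 the rule on leading genes, so these 3 stayed unnamed.

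Raw counts were summed per library and class, and a sum needed at least 20 cells. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr) in R 4.3.3, with the Benjamini-Hochberg method and a threshold of 0.05. The 3 treatment groups of 2 CD11 libraries shared 1 fit per class. Comparisons with cerebellum, with the intact CD45 library or with the CD11 knockout library used 1 fit over all groups. These groups have 1 library each, which is assumed to vary like the libraries of the other groups. The treatment effects in the microglia-like and macrophage-like classes were compared by the interaction term of a fit over both classes with library as a block. Class shares were tested with edgeR on cell counts with the total of cells used as library size. The interval of a share is the exact binomial (Clopper-Pearson) 95% interval, and the interval of a count per 1000000 UMIs of the sum (CPM) is the exact Poisson 95% interval. The CPM of tested genes use TMM-scaled library sizes, and those of marker sums, of Ccr2, Ptch1 and Trp53, and of the cerebellum and blood libraries use total UMIs. Both intervals cover counting error only, and a count of 0 was given a limit of 3 counts. Values without a test stand for the cerebellum and blood libraries, which have no replicates.

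A total of 18 gene lists were written before the data were examined. They cover interferon response, MHC class II presentation, MHC class I presentation, complement, disease-associated microglia, homeostatic microglia, inflammatory NF-kB, chemokines, immune suppression, immediate early and dissociation stress, cell cycle, p53 targets, SHH pathway, cholesterol and lipid handling, glycolysis and hypoxia, phagocytosis and scavenging, growth and matrix factors, and lymphocyte activation and checkpoints. Of the 18 genes of the homeostatic list, 12 are also markers by which clusters were named. Each list of at least 3 tested genes was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. No list passed with an estimated correlation in any comparison. In the cerebellum and blood libraries the median ratio of a list was ranked among 10000 random lists of matched abundance. The overlap of the effects of both treatments was set against 50 simulated data sets in which the treatments share their controls but no changes.

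Genes are named by a rule fixed before the data were examined. Among genes past the threshold with a mean of at least 20 CPM in the higher group, whose groups do not overlap, the rule takes the 10 with the largest change in each direction. It adds up to 4 genes of each list with the smallest p, and Ccr2, Ptch1 and Trp53 in every library. Between cerebellum and blood it takes the 10 largest ratios in each direction among genes with at least 100 counts and 50 CPM in the higher library. Hemoglobin, mitochondrial, sex-linked marker and antigen receptor genes and unnamed gene models are left out of the largest changes. Identifiers come from the files, and coordinates from the GENCODE vM21 annotation of build mm10.

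The fits were tested on simulated data with 200 changed genes. Of the changes of 4-fold, edgeR recovered 86.2% in the microglia-like class for GDC-0449 against untreated and 75.8% for radiation, and 63.6% and 87.9% in the macrophage-like class. For the Ccr2 comparison of CD45 libraries it recovered 26.6% in the microglia-like and 67.2% in the macrophage-like class. Between 1.79% and 8.33% of the calls were false in the comparisons within a class, and 11.7% and 2.48% in the interaction with GDC-0449 and with radiation. Each value came from 1 simulated data set in which every gene was drawn on its own, so shifts that many genes share are left out. DESeq2 1.42.0 was run beside edgeR. The other alternatives were relative log expression size factors, no filter on low counts, doublets kept, a strict cell filter (1000 UMIs, 500 genes, 5% mitochondrial), Leiden resolution 0.6 and 1.6, all groups in 1 fit, the irradiated CD45 libraries alone, other denominators for shares, and each replicate left out in turn.

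After the tests had been run, 678 barcodes were found in both the intact CD45 library and CD45 knockout replicate 2, where 41.7 were expected from the median rate of the other pairs of libraries. In 551 of them the copy in the intact library had at most 1/5 of the UMIs of its namesake (median 7.78%, quartiles 7.45% and 8.23%), and in 80 the copy in the knockout did (median 8.27%, quartiles 8.01% and 8.58%). Among the cells used there were 518 and 76 such copies. All cells were kept in the Ccr2 comparison, and leaving out the copies was added as an alternative.

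Replicate numbers follow the order of deposition and pair nothing. The labels do not say whether the 2 libraries of a group came from separate animals, and they give no batch or date. Groups of 2 libraries cannot reach p < 0.05 in an exact permutation test, which is why a model that pools the spread was used. Ambient RNA was not removed, since unfiltered barcodes were not used here.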

Results

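Transcripts of single cells were counted in 12 mouse libraries that fall into 8 groups. Of the tumor libraries sorted with CD11 beads, 2 came from untreated mice, 2 from mice given GDC-0449 (vismodegib, an inhibitor of the SHH receptor component Smoothened), 2 from irradiated mice and 1 from an irradiated Ccr2 knockout mouse or mice. Of the tumor libraries sorted with CD45 beads, all from irradiated mice, 1 had intact Ccr2 and 2 were Ccr2 knockouts. Cerebellum and blood of untreated mice of the tumor genotype gave 1 CD11 library each. The CD11 libraries with intact Ccr2 held between 9614369 and 27510209 UMIs, with medians of 4138 to 6388.5 UMIs per barcode. The CD11 knockout library held 12280924 UMIs (median 2493). The intact CD45 library held 11733499 UMIs (median 1403), and the CD45 knockout libraries held 15077436 (median 2700) and 18795858 (median 1695). After filtering, 31925 cells were used, from 1309 in GDC-0449 replicate 2 to 5637 in the intact CD45 library.

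Ccr2, the receptor through which monocytes leave the bone marrow (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557, build mm10), was still counted in the knockout libraries. Over all cells it stood at 25.3 CPM in the CD11 knockout library and at 48.0 and 24.8 CPM in the CD45 knockouts. With intact Ccr2 it stood at 198 and 211 CPM in the irradiated CD11 libraries, 212 CPM in the CD45 library, 81.1 and 185 CPM in untreated tumor, 54.2 and 148 CPM after GDC-0449, 77.8 CPM in cerebellum and 215 CPM in blood. In the macrophage-like class alone, Ccr2 was at 140 CPM in the intact CD45 library and at 74.5 and 74.8 CPM in the knockouts. The labels do not name the knockout allele, so it is unknown whether the counted 3' ends lie in the deleted part. Every library is labelled p53-/-, yet Trp53 was counted in all 12, between 12.8 and 42.8 CPM, and that allele is not named either. Ptch1 was between 0.335 and 8.98 CPM.

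The first question was how tumor-associated microglia and macrophages differ after treatment with GDC-0449 or radiation. Microglia-like cells made up 59.3% and 46.9% of cells in untreated tumor (mean 53.1% ± 8.75, SD, n = 2), 78.1% and 29.1% after GDC-0449 (53.6% ± 34.6), and 12.1% and 11.5% after radiation (11.8% ± 0.407). Cells named monocyte-derived macrophage-like, called macrophage-like here, made up 4.22% and 39.8% in untreated tumor (22% ± 25.1), 2.53% and 10.6% after GDC-0449 (6.57% ± 5.72), and 51.1% and 77.8% after radiation (64.5% ± 18.9). Their origin was not traced. The irradiated libraries lay below all other treatment libraries for microglia-like cells and above them for macrophage-like cells. Cells of the tumor or granule neuron lineage were 17.5% and 0.470% in untreated tumor, 3.99% and 1.6% after GDC-0449, and 0.0615% and 0% after radiation, where 0 of 2428 cells allows up to 0.124%. The CD11 beads select against this last class.

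No class passed the test of shares (edgeR on cell counts). The log2 fold change of the microglia-like share was -2.17 for radiation against untreated (SE 1.29, adjusted p = 0.498) and 0.01 for GDC-0449 (SE 1.24, adjusted p = 0.992). The macrophage-like share gave 1.55 for radiation (SE 1.55, adjusted p = 0.677), -1.74 for GDC-0449 (SE 1.56, adjusted p = 0.977) and 3.29 for radiation against GDC-0449 (SE 1.65, adjusted p = 0.393). The tumor lineage share gave -8.06 for radiation (SE 2.55, adjusted p = 0.166). Without untreated replicate 2, 1 class passed for radiation against untreated. Both folds of GDC-0449 against untreated changed sign without untreated replicate 2, to -0.15 and 0.64, and the microglia-like one also without GDC-0449 replicate 1, to -0.87, and the macrophage-like one at Leiden resolution 1.6, to 2.51. The clusters within a class also differed. Of the microglia-like cells, cluster 6 held 33.6% and cluster 7 held 27.8% in untreated replicate 1, clusters 7 and 17 held 41.1% and 41.2% in untreated replicate 2, and clusters 6 and 7 held 74.3% and 23.005% in GDC-0449 replicate 1. Cluster 20 held 90.8% of them in GDC-0449 replicate 2 and 69.0% and 72.5% in the irradiated libraries. Cluster 22, which stayed unnamed between the border-associated (score 0.579) and monocyte-derived macrophage lists (0.4345) and is in neither share, held 40.0% of all cells of GDC-0449 replicate 2, 3.01% and 1.73% of the irradiated cells, and at most 1 cell in any other library.

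**Figure D1:**
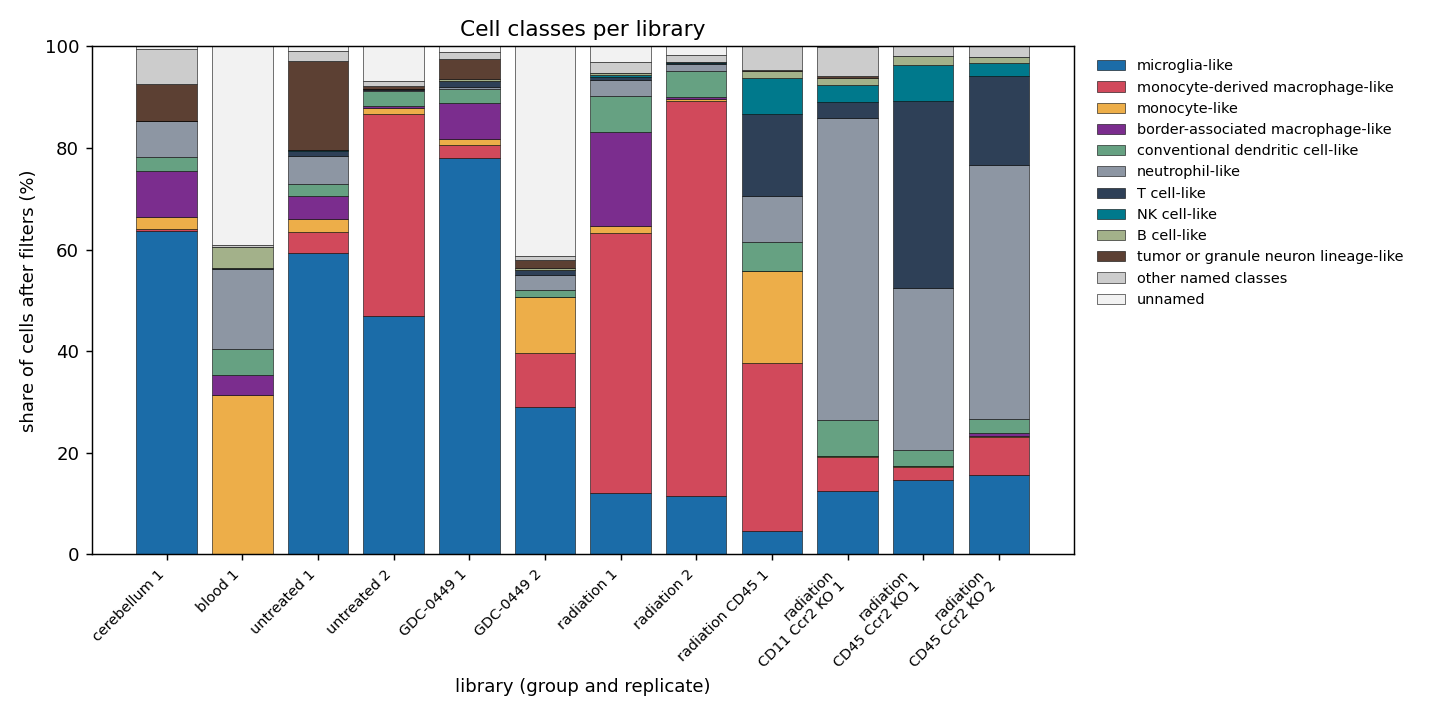
Share of cells (percent, y axis) by cell class in each of the 12 libraries (x axis), as stacked bars from 0. Microglia-like cells were 12.1% and 11.5% in the irradiated CD11 libraries with intact Ccr2, against 46.9% and 59.3% in untreated tumor.

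In microglia-like cells, genes of cell division fell after GDC-0449. Lockd, a long non-coding RNA (ENSMUSG00000098318, chromosome 6, 134929092 to 134956798), went from 17.1 and 29.2 CPM to 1.71 and 1.16 CPM (log2 fold change -3.90, SE 0.38, edgeR adjusted p = 0.0313). The mitotic kinase gene Pbk fell by 3.88 on the log2 scale (SE 0.45, adjusted p = 0.0408). Cdkn3, a phosphatase of cyclin-dependent kinases, fell by 3.63 (SE 0.39, adjusted p = 0.0313). Cdca3, needed for entry into mitosis (ENSMUSG00000023505, chromosome 6, 124829547 to 124833701), fell from 33.0 and 46.7 CPM to 4.06 and 2.90 CPM. These are 4 of the 6 genes called of 10956 tested, all lower. The other 2 were Prc1 and the hemoglobin gene Hbb-bt, named after their values were seen. Erythroid marker RNA in these sums was 984 and 2895 CPM in untreated tumor against 0.627 and 13.4 CPM after GDC-0449.

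As a list, cell cycle genes fell in the microglia-like class after GDC-0449, with a median log2 fold change of -2.49 and all 20 tested genes lower (camera adjusted p = 6.8e-48). With an estimated correlation the adjusted p was 0.41. None of them passed over all genes tested and 17 passed adjusted over the list alone. Mki67, the proliferation marker, gave -3.20 (adjusted p = 0.0597). The cycling cluster 24 held 99 and 218 cells in untreated tumor and 9 and 2 cells after GDC-0449, and without it no gene was called and the list median was -1.02. The disease-associated microglia list had a median of -0.60 (camera adjusted p = 8.2e-05, and adjusted p = 0.47 with an estimated correlation), with 5 genes lower adjusted over the list alone. Immediate early and dissociation stress genes had a median of 1.27, with 21 of 22 genes higher (camera adjusted p = 3.4e-09, and adjusted p = 0.47 with an estimated correlation). The count of 6 became 1 without either untreated library, 328 without GDC-0449 replicate 1 and 69 without replicate 2, and DESeq2 called 154 genes.

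After radiation, microglia-like cells had less RNA of homeostatic microglia genes. Olfml3, a secreted protein enriched in microglia (ENSMUSG00000027848, chromosome 3, 103722222 to 103738001), fell from 563 and 622 CPM to 118 and 75.0 CPM (log2 fold change -2.62, SE 0.28, adjusted p = 0.0456). Ly6c2, a surface antigen of inflammatory monocytes (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), rose from 32.2 and 43.4 CPM to 194 and 155 CPM (2.21, SE 0.24, adjusted p = 0.0456). The homeostatic list fell with all 18 genes lower and a median of -1.44 (camera adjusted p = 6e-21, and adjusted p = 0.42 with an estimated correlation), with 1 gene past the threshold over all genes tested and 13 adjusted over the list alone. Sparc, a matrix glycoprotein, gave -2.73 (adjusted p = 0.0864) and the purine receptor gene P2ry12 gave -2.51 (adjusted p = 0.0879). Since 12 of the 18 genes are naming markers, the class was in part defined by them. The naming markers of microglia summed to 14259 and 11692 CPM in untreated tumor and to 5120 and 4714 CPM after radiation, and the macrophage markers to 7087 and 6279.6 CPM and then 4977 and 7860 CPM. Outside cycling cluster 24, microglia markers had more counts than macrophage markers in 86.2% and 87.6% of the untreated and 69.7% and 40.9% of the irradiated microglia-like cells, so a change within cells was not separated from a change in the make-up of the class.

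Genes listed as p53 targets had a median log2 fold change of 0.63 in irradiated microglia-like cells (camera adjusted p = 0.019, and adjusted p = 0.42 with an estimated correlation). None passed over all genes tested and 1 rose adjusted over the list alone. Cdkn1a, an inhibitor of cell division, gave 1.55 (adjusted p = 0.109). The mice are labelled p53-/- while Trp53 was still counted, and whether p53 acted in these cells was not tested. Glycolysis and hypoxia genes had a median of -0.63 (camera adjusted p = 0.0013, and adjusted p = 0.42 with an estimated correlation), with 1 higher and 6 lower adjusted over the list alone. Of 10956 genes, 3 were called, and the third was Hbb-bt, named after its value was seen. DESeq2 called 345. The edgeR count was 0 without untreated replicate 2 or either irradiated library, 1 without untreated replicate 1, 0 with relative log expression size factors and 0 without cycling cluster 24 (1995 genes at an unadjusted p under 0.05).

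Set against each other, the irradiated microglia-like sums had more cell division RNA than those given GDC-0449, and it came with cycling cluster 24. In that cluster the microglia and macrophage markers summed to 2201 and 7092 CPM in irradiated replicate 1 and to 4887 and 8886 CPM in replicate 2, against 10925 and 7027 CPM and 10540 and 6695 CPM in untreated tumor. In the other microglia-like cells of the irradiated libraries they summed to 6472 and 3998 CPM in replicate 1 and to 4684 and 7678 CPM in replicate 2, so the irradiated class is not clearly microglia alone, in cluster 24 or outside it. Ccnb2, a cyclin of mitosis (ENSMUSG00000032218, chromosome 9, 70407692 to 70421547), was at 93.4 and 31.3 CPM after radiation and at 2.14 and 2.90 CPM after GDC-0449 (log2 fold change 4.66, SE 0.57, adjusted p = 0.0295). Ccna2, Cdc20 and Mki67 were higher by 4.95, 4.37 and 3.59 on the log2 scale. All 20 cell cycle genes were higher, 11 of them past the threshold over all genes tested and 17 adjusted over the list alone (median 2.86, camera adjusted p = 1.9e-44, and adjusted p = 0.29 with an estimated correlation). Slfn4, an interferon-induced gene of myeloid cells, was higher by 4.62 (SE 0.49, adjusted p = 0.0219). Chemokines had a median of 0.79 (camera adjusted p = 0.0012, and adjusted p = 0.29 with an estimated correlation), with 6 higher and 2 lower adjusted over the list alone.

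The 4 genes lower after radiation than after GDC-0449 were Sparc (-2.24, SE 0.36, adjusted p = 0.049), Slco2b1, an organic anion transporter (-2.15), Tln2 (-1.86) and Crybb1 (-1.79). All 18 homeostatic genes were lower, 2 past the threshold over all genes tested and 16 adjusted over the list alone (median -1.30, camera adjusted p = 1.9e-19, and adjusted p = 0.29 with an estimated correlation). In all, 52 of 10956 genes were called, 48 higher and 4 lower, and DESeq2 called 290, all 52 among them. The count fell to 0 without the cycling cluster, of which the irradiated libraries held 32 and 26 cells, and Mki67 then gave -0.24. It was 0 without radiation replicate 1, 88 without radiation replicate 2 and 608 without GDC-0449 replicate 2.

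Macrophage-like cells had less RNA for chemokines of T cell recruitment after GDC-0449. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) fell from 176 and 201 CPM to 0 and 3.21 CPM (log2 fold change -6.31, SE 0.52, adjusted p = 0.00456). Cxcl10, which binds the same receptor, fell from 435 and 535 CPM to 21.8 and 0 CPM (-6.26, SE 0.79, adjusted p = 0.0393). Il1rn, the interleukin 1 receptor antagonist (-3.31), the costimulatory receptor gene Cd40 (-3.05), Ifi205 (-2.96), Tgm2 (-2.60) and the complement gene C3 (-2.45) also fell. Dnase1l3, which encodes a secreted DNase, was at 0 in both GDC-0449 libraries and at least 23.7-fold lower. Iqgap2 rose (2.14, SE 0.29, adjusted p = 0.0429). In all, 11 of 9973 genes were called, 1 higher and 10 lower, and DESeq2 called 43, with 10 in common.

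Among the lists, interferon response genes had a median log2 fold change of -0.68 after GDC-0449 in the macrophage-like class (camera adjusted p = 1.1e-08, and adjusted p = 0.44 with an estimated correlation), with 1 gene past the threshold over all genes tested and 7 adjusted over the list alone. Chemokines had a median of -0.59 (adjusted p = 8.4e-05, and adjusted p = 0.33 with an estimated correlation), with 2 lower over all genes tested, and 3 lower and 2 higher adjusted over the list alone. SHH pathway genes had a median of -1.41 over 5 tested genes (adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation), with none past the threshold over all genes tested and 1 adjusted over the list alone. Of this list 2 genes are naming markers, and tumor or granule neuron lineage marker RNA in these sums was 82.2 and 26.2 CPM in untreated tumor and 26.7 and 8.84 CPM after GDC-0449. Lymphocyte activation and checkpoint genes had a median of -1.05 over 4 genes (adjusted p = 0.0012, and adjusted p = 0.33 with an estimated correlation), with none over all genes tested and 2 lower adjusted over the list alone. The groups drew on different clusters: cluster 8 held 98.6% and 92.8% of untreated macrophage-like cells and 68.9% of those of GDC-0449 replicate 1, and cluster 2 held 90.6% of those of replicate 2. GDC-0449 replicate 1 had 45 macrophage-like cells and untreated replicate 1 had 71. The count of 11 became 224 without GDC-0449 replicate 1, 2 without replicate 2, 60 and 2 without untreated replicates 1 and 2, and 0 with the strict cell filter, under which the interferon median was 0.50.

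Macrophage-like cells had more RNA of Fkbp5, Tsc22d3 and Klf9 after radiation. Fkbp5, an immunophilin that binds steroid receptor complexes (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), rose from 6.80 and 11.2 CPM to 168 and 138 CPM (log2 fold change 3.91, SE 0.63, adjusted p = 0.031). Tsc22d3, a leucine zipper protein (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), rose from 59.9 and 56.0 CPM to 375 and 402 CPM (2.75, SE 0.35, adjusted p = 0.0158). The transcription factor gene Klf9 rose by 4.63, the mTOR regulator gene Ddit4 by 3.54, and the fatty acid binding protein gene Fabp4 by 4.77. High values were not limited to irradiated libraries. By total UMIs, Fkbp5 was at 135 CPM and Klf9 at 76.2 CPM in GDC-0449 replicate 2, against 14.8 and 5.94 CPM in replicate 1. Lcn2, a lipocalin abundant in neutrophils, rose by 4.12, while neutrophil marker RNA in these sums was 683 and 1338 CPM in untreated tumor and 6670 and 2811 CPM after radiation.

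Cxcl9 fell after radiation too, to 6.37 and 4.08 CPM (log2 fold change -5.21, SE 0.33, adjusted p = 0.000497). Dnase1l3 fell by 4.68, the Notch target Hes1 by 4.63, the ubiquitin ligase subunit gene Asb2 by 4.44 and the toll-like receptor gene Tlr12 by 3.79. Genes of MHC class II presentation fell together, with a median of -1.52 and all 9 lower (camera adjusted p = 4.1e-11, and adjusted p = 0.57 with an estimated correlation). Of these, 2 passed over all genes tested and 9 adjusted over the list alone. Ciita, their master regulator, fell from 46.3 and 31.7 CPM to 4.25 and 8.06 CPM (-2.52, SE 0.44, adjusted p = 0.0336), and H2-DMa, which loads peptides, fell by 1.52 (adjusted p = 0.0419). H2-Ab1 gave -1.95 (adjusted p = 0.0781). Cell cycle genes, without the cells of cycling cluster 24, which was named microglia-like as a whole, had a median of -0.71 (camera adjusted p = 3.4e-07, and adjusted p = 0.57 with an estimated correlation), with 3 lower over all genes tested and 6 adjusted over the list alone. Inflammatory NF-kB genes had a median of -0.66 (camera adjusted p = 0.025, and adjusted p = 0.75 with an estimated correlation), with 1 lower over all genes tested, and 5 lower and 1 higher adjusted over the list alone.

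Microglial genes fell in irradiated macrophage-like cells as well. Sparc fell from 178 and 324 CPM to 33.0 and 32.4 CPM, Olfml3 from 220 and 224 CPM to 39.0 and 22.7 CPM, and Siglech by 2.69 on the log2 scale. The homeostatic list had a median of -0.96 (camera adjusted p = 1e-10, and adjusted p = 0.57 with an estimated correlation), with 5 genes lower over all genes tested and 8 adjusted over the list alone. Conventional dendritic cell-like sums, a class not known for these genes, moved with them, with Sparc at 357 and 274 CPM in untreated tumor and at 9.14 and 16.8 CPM after radiation. Of 9973 genes, 143 were called, 43 higher and 100 lower, and DESeq2 called 157, with 104 in common. The macrophage-like cells came from cluster 8 in untreated tumor (98.6% and 92.8%) and mostly from clusters 2 (64.8% and 82.4%) and 19 after radiation. The count was 140 and 16 without untreated replicates 1 and 2, 0 without radiation replicate 1, 1 without radiation replicate 2, and 1 with 1 round of clusters.

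Sums of conventional dendritic cell-like cells, few as they were (41 and 88 cells in untreated tumor, 117 and 125 after radiation), also changed in Fkbp5, Ddit4, Sparc and Olfml3. No test compared this class with the macrophage-like one. Fkbp5 rose from 8.85 and 9.40 CPM to 224 and 150 CPM (log2 fold change 4.32, SE 0.40, adjusted p = 0.00236), Ddit4 rose by 3.83 (adjusted p = 0.00236) and Il1r2, the decoy receptor of interleukin 1, by 3.55 (adjusted p = 0.0334). Gpr171, an orphan receptor, rose by 3.57 and Pik3ip1, a kinase inhibitor, by 4.15. The microglial genes Sparc (-4.60, adjusted p = 0.00148), Fcrls (-3.77) and Olfml3 (-4.70) and the tetraspanin gene Cd81 (-3.50) fell. In all, 45 of 6450 genes were called by edgeR, 27 higher and 18 lower, and DESeq2 called 47. The count was 235 and 358 without untreated replicates 1 and 2, 88 without radiation replicate 2, 12 at Leiden resolution 1.6 and 11 with 1 round of clusters.

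**Figure D2:**
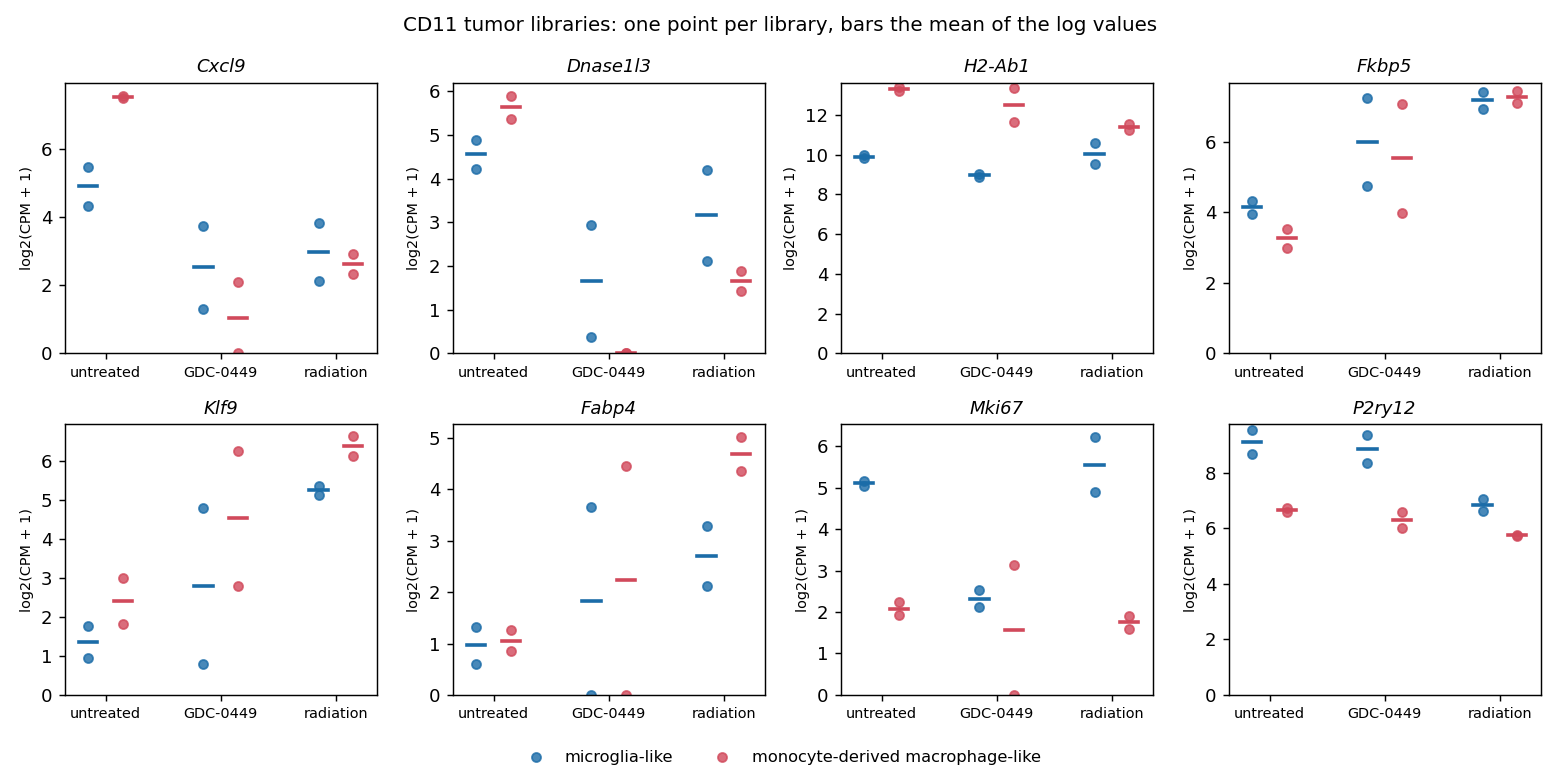
Log2 of CPM plus 1 (y axis) for named genes in summed microglia-like and macrophage-like cells of the CD11 tumor libraries, with 1 point per library and bars at the mean of the log values. CPM here are over total UMIs, without TMM scaling. Fkbp5 in irradiated macrophage-like cells stood at 174 and 137 CPM, against 6.97 and 10.6 CPM in untreated tumor.

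Between radiation and GDC-0449, no gene of 9973 was called in the macrophage-like class by edgeR, 692 had an unadjusted p under 0.05, and DESeq2 called 12. MHC class II genes had a median log2 fold change of -1.25 (camera adjusted p = 3.4e-08, and adjusted p = 0.51 with an estimated correlation), with 7 lower adjusted over the list alone and none over all genes tested. Interferon response genes had a median of 0.65 (adjusted p = 4e-07, and adjusted p = 0.51 with an estimated correlation), with 2 higher adjusted over the list alone and none over all genes tested. Immune suppression genes had a median of -0.00174, a mean of 0.39 and an upward call (adjusted p = 0.048, and adjusted p = 0.51 with an estimated correlation). The count was 3 and 20 without GDC-0449 replicates 1 and 2.

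For some genes the change after treatment differed between the classes, as tested by the interaction of class and treatment. After radiation, 137 of 11260 genes differed, 24 with the higher change in macrophage-like cells and 113 with the lower one. MHC class II genes had a median difference of -1.65 on the log2 scale, macrophage-like minus microglia-like, with 6 of 9 past the threshold over all genes tested and 8 adjusted over the list alone (camera adjusted p = 4.4e-13, and adjusted p = 0.29 with an estimated correlation). Cell cycle genes had a median difference of -1.36, with 5 and 11 genes (adjusted p = 4.4e-13, and adjusted p = 0.29 with an estimated correlation), but cycling cluster 24 was named microglia-like as a whole. Without that cluster the count was 76, and the differences of the cyclins Ccna2 and Ccnb2 were -0.47 and -0.62 in place of -3.88 and -3.42. Of the MHC class II genes, Ciita (-2.27, adjusted p = 0.347) and H2-Ab1 (-1.29, adjusted p = 0.0693) were not called without it. Growth and matrix factors had a median difference of -0.69, with 2 and 7 genes (camera adjusted p = 1.9e-05, and adjusted p = 0.29 with an estimated correlation). Of this list 5 genes are naming markers, 4 of them for macrophages, so the classes were in part defined by them. The count after radiation was 359 without untreated replicate 1 and 225 without radiation replicate 1. After GDC-0449, 5 genes differed, and interferon response genes had a median difference of -0.66, with 1 gene over all genes tested and 8 adjusted over the list alone (adjusted p = 4.7e-12, and adjusted p = 0.44 with an estimated correlation). DESeq2 called 72 and 1. The count after GDC-0449 was 176 and 45 without untreated replicates 1 and 2, 17 and 11 without GDC-0449 replicates 1 and 2, 2 with doublets kept or with the strict cell filter, and 0 at Leiden resolution 0.6 or with 1 round of clusters (343 and 471 at an unadjusted p under 0.05).

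Whether both treatments moved the same genes was asked against simulated data with shared controls and no changes. In macrophage-like cells, Il1rn, Spint1, Cd40, Cxcl9, Dnase1l3 and Serpina3g fell after both treatments. The log2 fold changes of the 2 treatments correlated across genes at 0.60, against 0.30 in the simulations (SD 0.0191 over 50 draws). In microglia-like cells only Hbb-bt fell after both, and the correlation was 0.44 against 0.39 (SD 0.0157). Genes are not independent replicates, and the 2 untreated libraries enter both comparisons, so part of each correlation may be theirs. The simulations drew each gene on its own, so their SD leaves out shifts that many genes share, such as a change of clusters. GDC-0449 replicate 2, which lay nearer to the irradiated libraries than to replicate 1, also enters the correlations. The microglia-like correlation was -0.11 at Leiden resolution 0.6 and -0.02 with 1 round of clusters.

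Against cerebellum without a tumor label, microglia-like cells of untreated tumor had more RNA of interferon response genes. Rsad2, an antiviral enzyme (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), stood at 72.4 and 168 CPM in tumor and at 2.54 CPM in cerebellum (log2 fold change 5.55, SE 0.65, adjusted p = 0.0116). Cmpk2 was higher by 6.39 on the log2 scale, the interferon-induced gene Ifit3 by 4.61 and the transcription factor gene Irf7 by 4.54. All 23 interferon response genes were higher, 14 past the threshold over all genes tested and 21 adjusted over the list alone (median 3.77, camera adjusted p = 7e-53, and adjusted p = 0.15 with an estimated correlation). All 11 MHC class I genes were higher, 3 over all genes tested and 10 adjusted over the list alone (median 1.91, camera adjusted p = 1.5e-15, and adjusted p = 0.17 with an estimated correlation). Of 9 MHC class II genes, 4 rose over all genes tested and 6 adjusted over the list alone (median 1.27, camera adjusted p = 1.7e-09, and adjusted p = 0.17 with an estimated correlation). Among them, Cd74, the invariant chain, was at 2796 and 3210 CPM against 482 CPM. Macrophage marker RNA in these microglia-like sums moved too, from 2269.5 CPM in cerebellum to 7087 and 6279.6 CPM in tumor, and H2-Ab1, at 925 and 1216 CPM in the tumor sums, was at 9191 and 11325 CPM in macrophage-like ones. Complement genes had a median of 0.79 (camera adjusted p = 0.0051, and adjusted p = 0.23 with an estimated correlation), with none over all genes tested, and 4 higher and 1 lower adjusted over the list alone.

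Microglia-like cells of cerebellum had more of Ctsk, a lysosomal protease (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), at 57.7 CPM against 0.130 and 0.156 CPM in tumor (log2 fold change -8.35, SE 0.54, adjusted p = 0.000186). The chemokine gene Cxcl1 gave -6.05 and Gadd45b -2.48. The homeostatic genes Crybb1 (-2.06) and P2ry13 (-1.59) were also higher in cerebellum. The homeostatic list had a median of -1.10, with 2 of 18 genes over all genes tested and 7 adjusted over the list alone (camera adjusted p = 5.4e-09, and adjusted p = 0.23 with an estimated correlation). In all, 62 of 11143 genes were called, 48 higher in tumor and 14 lower, and DESeq2 called 180, with 58 in common. The count was 105 without untreated replicate 1 and 4 without replicate 2, and the direction of Gadd45b turned at Leiden resolution 0.6 (0.63). Tissue and mouse age (2 against 8 weeks) differ together here, under the same labelled genotype, and cerebellum is 1 library, of whose microglia-like cells 91.2% fell in cluster 15.

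The cerebellum and blood libraries were compared as wholes, without replicates or a test. Unnamed cluster 5, led by Prg4, held 39.0% of the blood cells, and cerebellum held 100 cells of the tumor or granule neuron lineage and 91 choroid or ependymal-like cells. Ttr, the thyroxine carrier made by the choroid plexus, was at 28991 CPM (interval 28882 to 29101) in cerebellum and 1.0 CPM in blood. Sparc was at 2328 and 0.620 CPM, the microglial lectin gene Siglech at 332 CPM (interval 320 to 344) and 0.0775 CPM (interval 0.00938 to 0.280), and Olfml3 at 437 and 0.387 CPM. Ecscr was at 189 CPM in cerebellum, at least 1626-fold higher than its limit in blood. Blood was higher in Prg4, the lubricant proteoglycan (2836 against 14.7 CPM), the acute-phase gene Saa3 (1799 against 9.37 CPM), Selp (127 against 0.754 CPM), Arg1 (125 against 0.754 CPM), the scavenger receptor gene Marco (83.9 against 0.646 CPM) and the B cell gene Cd79a (83.9 against 0.538 CPM). Homeostatic microglia genes had a median log2 ratio of 6.20, above all 10000 random lists. SHH pathway genes had a median of 4.32 (percentile 99.97), and interferon response genes a median of -0.39 (percentile 0.0200). Microglia-like cells were 63.7% of cerebellum (interval 61.1% to 66.2%) and monocyte-like cells 31.2% of blood.

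The second question was what loss of Ccr2 does to the myeloid cells of irradiated tumors. Monocyte-like cells were 18.2% of the intact CD45 library (interval 17.2% to 19.2%) and 0.211% and 0.190% of the knockouts (mean 0.20% ± 0.0150, SD, n = 2). Of the 1026 intact monocyte-like cells, 1019 fell in cluster 13, which held 1034 cells over all libraries. The irradiated CD11 libraries, sorted with other beads and counted on the smaller gene set, had intact Ccr2 and held only 24 of 1627 and 5 of 2428 monocyte-like cells. Their lowest UMI counts of a barcode were 2273 and 2278, against 500 in the intact CD45 library. The monocyte-like cells of the latter had a median of 1646 UMIs, so the CD11 pair may lack part of such cells. Macrophage-like cells were 33.0% with intact Ccr2 (interval 31.8% to 34.2%) and 2.63% and 7.37% in the knockouts. Neutrophil-like cells were 8.89% and then 31.8% and 50.1%, microglia-like cells 4.63% and then 14.6% and 15.7%, and T cell-like cells 16.3% and then 36.8% and 17.4%. No class passed (edgeR). The log2 fold change was -6.48 for monocyte-like cells (SE 1.86, adjusted p = 0.103), -2.72 for macrophage-like cells (SE 1.6, adjusted p = 0.698) and 2.20 for neutrophil-like cells (SE 2.08, adjusted p = 0.698). The monocyte-like fold changed sign with the strict cell filter (0.34) and with 1 round of clusters (0.08), and the macrophage-like one with TMM over classes (0.34). Cluster 12, with scores of 0.2499 on the microglia and 0.0098 on the macrophage list, just past the lead a name needs, held 44.1% of the intact and 86.3% and 63.7% of the knockout microglia-like cells. The intact library and knockout replicate 2 held 678 barcodes in common, where 41.7 were expected, and the smaller copy of a barcode made up 48.7% of the intact neutrophil-like cells. Without these copies the neutrophil-like share of the intact library was 5.02%, the macrophage-like 33.3% and the monocyte-like 20.04%, and the log2 fold change of the neutrophil-like share was 3.04 (adjusted p = 0.573).

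Macrophage-like cells of the knockouts had more Vcan and S100a4 and less of the lipid carrier Apoe. Vcan, the matrix proteoglycan versican (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509), was at 58.3 and 48.4 CPM against 2.37 CPM with intact Ccr2 (log2 fold change 4.44, SE 0.60, adjusted p = 0.0261). S100a4 rose by 3.67, Acod1, which makes itaconate, by 3.51, the protease inhibitor gene Slpi by 3.18 and vimentin (Vim) by 3.00. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) fell from 99760 CPM to 27428 and 23685 CPM (-1.96, SE 0.25, adjusted p = 0.0261), and the cholesterol exporter gene Abca1 fell by 1.95 (adjusted p = 0.0483). Crybb1 fell by 3.45 and the transcription factor gene Bhlhe41 by 3.34. Neutrophil marker RNA in these sums was 2257 CPM with intact Ccr2 and 4620 and 36486 CPM in the knockouts, and microglial marker RNA was 2403 CPM and then 954 and 985 CPM. The astrocyte marker Aldoc and the oligodendrocyte marker Mbp were among the leading genes of cluster 3, which held most intact macrophage-like cells. Mbp was also lower in knockout B cell-like sums (log2 fold change -2.57), and Mobp in NK cell-like sums (-3.74). How far RNA of other brain cells bears on the falls here was not tested.

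Cholesterol and lipid handling genes had a median log2 fold change of -0.93 in the macrophage-like cells without Ccr2 (camera adjusted p = 0.0008, and adjusted p = 0.28 with an estimated correlation), with 2 lower over all genes tested and 6 adjusted over the list alone. Glycolysis and hypoxia genes had a median of 0.88 (adjusted p = 9.9e-05, and adjusted p = 0.45 with an estimated correlation), with 1 higher over all genes tested, Gapdh (1.97), and 7 adjusted over the list alone. Phagocytosis and scavenging genes had a median of -1.04 (adjusted p = 0.094), with 1 lower over all genes tested, and 6 lower and 2 higher adjusted over the list alone. In all, 47 of 10346 genes were called, 16 higher and 31 lower, and DESeq2 called 167, with 37 in common. Cluster 3 held 90.8% of the intact macrophage-like cells, and cluster 23 held 68.0% and 88.4% of the knockout ones, with median depths of 1674 UMIs per cell against 9222.5 and 6862. Without the shared barcodes 142 genes were called, all 47 among them. The count was 174 without knockout replicate 1, 2 without replicate 2, and 0 with doublets kept, with the irradiated CD45 libraries alone or with 1 round of clusters.

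In microglia-like cells the loss of Ccr2 gave no called gene of 11143 by edgeR in the CD45 libraries. At an unadjusted p under 0.05 there were 1042, and DESeq2 called 35. All 9 MHC class II genes were lower, with a median log2 fold change of -1.21 (camera adjusted p = 4.9e-08, and adjusted p = 0.29 with an estimated correlation), 5 of them adjusted over the list alone and none over all genes tested. Cd74 gave -1.92 (adjusted p = 0.379) and H2-Aa gave -1.51. Cell cycle genes had a median of -1.17 and a mean of -0.52 (adjusted p = 5e-07, and adjusted p = 0.59 with an estimated correlation), with 7 lower adjusted over the list alone and none over all genes tested. The cycling cluster 24 held 16.9% of the intact microglia-like cells, with microglia markers at 2132 CPM and macrophage markers at 8969 CPM there, and 1.08% and 3.14% of the knockout ones, and without it the list median was 0.035 (adjusted p = 0.915). Growth and matrix factors had a median of 1.16 (adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation), with none past either threshold. In these sums neutrophil marker RNA was 1064 CPM with intact Ccr2 and 3601 and 7566 CPM in the knockouts, and macrophage marker RNA was 6879 CPM and then 4299 and 3829 CPM.

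Of the other classes of the CD45 libraries, NK cell-like and B cell-like cells had called genes, among them neutrophil genes. S100a9, a calcium-binding protein abundant in neutrophils, was higher in the knockouts by 4.41 in NK cell-like, 3.00 in B cell-like and 4.67 in conventional dendritic cell-like sums, and S100a8 by 4.00 in NK cell-like and 2.42 in B cell-like sums. NK cell-like sums also had more Cxcl2, a chemokine for neutrophils (4.25), and less of the chemokine Ccl1 (-3.43, 5.14 and 54.6 CPM against 285 CPM). The neutrophil marker Ngp was higher in the same sums (5.81). Ambient RNA was not removed, and neutrophil-like cells were a larger share of the knockouts. Whether the Cxcl2 RNA came from NK cells was not tested. The oligodendrocyte genes Mobp (-3.74) in NK cell-like and Mbp (-2.57) in B cell-like sums were lower too. In NK cell-like cells 166 of 6357 genes were called, 98 higher and 68 lower, with 1 residual degree of freedom, and DESeq2 called 38. The count was 0 with doublets kept, 22 with the strict cell filter, 18 with the irradiated CD45 libraries alone and 111 without the shared barcodes. B cell-like cells gave 18 of 4066 genes, 9 in each direction (DESeq2 2, and 43 without the shared barcodes), and conventional dendritic cell-like cells gave S100a9 alone of 7970 (DESeq2 90). No gene was called by edgeR in neutrophil-like cells (308 of 8590 at an unadjusted p under 0.05, and none by DESeq2) or in T cell-like cells (510 of 10055, and 10 by DESeq2). Without CD45 knockout replicate 2, 104 genes were called in neutrophil-like and 38 in conventional dendritic cell-like cells, and without replicate 1, 3 and 8.

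The CD11 knockout library was set against the irradiated CD11 pair with intact Ccr2. Neutrophil-like cells were 59.3% of it, against 3.07% and 1.36%, and macrophage-like cells 6.58%, against 51.1% and 77.8%. The lowest UMI count of a barcode was 501 in the knockout library and 2273 and 2278 in the pair. Median UMIs of the knockout library's neutrophil-like and microglia-like cells were 2367 and 1456.5, near or below those minima, so the pair may lack part of such cells. Neither share passed (edgeR log2 fold change 4.74 with adjusted p = 0.235, and -3.29 with adjusted p = 0.255). Among the largest changes, Pgk1, a glycolytic enzyme (ENSMUSG00000062070, chromosome X, 106187100 to 106203699), was higher by 5.04 in microglia-like and 5.14 in macrophage-like cells, and Jchain by 8.29 in the latter. The cytokine gene Il1b, a leading gene of neutrophil-like cluster 1, was higher by 2.34 in microglia-like cells (SE 0.31, adjusted p = 0.0127), whose neutrophil marker RNA was 6765 CPM against 1407 and 547 CPM. Cluster 12 held 74.8% of these cells in the knockout, and cluster 20 held 69.0% and 72.5% in the pair. Cell cycle genes had a median of 1.51 in macrophage-like cells, with none over all genes tested and 8 adjusted over the list alone (camera adjusted p = 3.2e-09, and adjusted p = 0.058 with an estimated correlation). Cluster 23 held 30.8% and cluster 2 held 29.5% of the knockout macrophage-like cells, against 0.361% and 0.371% and against 64.8% and 82.4% in the pair, and neutrophil marker RNA was 9230.4 CPM against 6670 and 2811 CPM. In all, 20 of 11143 genes were called in the microglia-like and 45 of 10346 in the macrophage-like class.

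The knockout library was counted on the larger gene set and the CD11 pair on the smaller one, and their lowest UMI counts differed too. Genotype and processing thus cannot be told apart by this comparison alone. The intact CD45 library shares the larger gene set, and set against the same CD11 pair it moved 20 of the 20 and 42 of the 45 called genes the same way, with 10 and 38 of them called. Ccr2, called lower in the knockout macrophage-like cells (-2.13, adjusted p = 0.0344), was not called there (-0.39, adjusted p = 0.772). Pgk1 gave 4.43 in both classes there, and Il1b gave 0.26 in microglia-like cells (adjusted p = 0.834). Over all genes tested, 63.5% and 58.7% moved the same way. The microglia-like count was 9 without either irradiated replicate, and the macrophage-like count was 14 and 8 without replicates 1 and 2.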

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

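The tests of depth per cell, of dissociation stress, of neutrophil RNA gene by gene and of the level of macrophage genes in other blood clusters were chosen only after the results were seen, and Per1 was given its own test after its value was known. The other tests were written before, except that a margin of 2 SD for the depth ratio was added after a first value was seen. 

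The effect of treatment differed between macrophage-like and microglia-like cells, by the interaction test, for 137 genes after radiation and for 5 after GDC-0449. All differences here are log2 fold changes in macrophage-like minus microglia-like cells, and the simulated data gave 2.48% false calls for radiation and 11.7% for GDC-0449. Each rate came from 1 simulated data set in which every gene was drawn on its own. The rates thus leave out shifts that many genes share, such as a change of clusters, and do not give the false share of the calls here. After radiation the differences were -3.25 for the chemokine gene Cxcl9, -2.15 for Ccl9, -3.00 for Ciita, -1.89 for H2-Ab1 and -3.24 for the complement gene Cfp. They were -3.34 for Dnase1l3, -3.33 for Hes1, -2.38 for Asb2 and -1.76 for Rsad2. The cyclins Ccna2 and Ccnb2 differed by -3.88 and -3.42, but cycling cluster 24 was named microglia-like as a whole. Without it 76 genes differed, the cyclins stood at -0.47 and -0.62, and Cxcl9 (-1.66), Ccl9 (-0.97), Ciita (-2.27), H2-Ab1 (-1.29) and Dnase1l3 (-2.58) were not called. The protease gene Ctsd (1.17), the purine receptor gene P2ry12 (1.49) and the prion protein gene Prnp (1.79) differed in the other direction. After GDC-0449 the differences were -3.77 for Cxcl10, -2.24 for Spint1, -2.85 for the heat shock gene Hspa1a, -1.52 for Lag3 and 2.30 for Ttr, which choroid plexus makes in large amounts. The sign of Ttr turned without untreated replicate 1 (-1.44) and without GDC-0449 replicate 2 (-2.32), that of Rsad2 with the strict cell filter (0.96) and that of Prnp with 1 round of clusters (-0.039). After GDC-0449 no gene differed by edgeR at Leiden resolution 0.6 or with 1 round of clusters (343 and 471 at an unadjusted p under 0.05), and DESeq2 at the settings of the report called 1.

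Unnamed cluster 22 held 523 cells of GDC-0449 replicate 2, and the GDC-0449 libraries differed from each other more than any other pair of replicates in the share of microglia-like cells (78.1% and 29.1%). One candidate explanation is that this library is an irradiated one, since its microglia-like cells fell in the cluster of the irradiated libraries. With sums thinned to 1 depth, its distance to the irradiated microglia-like sums was 1.35 times the distance between those 2 libraries. This ratio lay between the bounds set for and against, and the macrophage-like ratio was 1.28. In microglia-like sums GDC-0449 replicate 2 lay nearer to the irradiated libraries (root mean square log2 difference 0.595 and 0.515) than to replicate 1 (0.6496). The macrophage-like distances were 0.645 and 0.5996, against 0.853 to replicate 1. However, cycling cluster 24 held 0.525% of the microglia-like cells of GDC-0449 replicate 2 (0.647% in replicate 1). It held 16.2% and 9.29% in the irradiated pair, so this share runs with the label. Depth is excluded for the shares and clusters, since median UMIs differed by a factor of at most 1.05 per barcode or per microglia-like cell (at least 1.54 in the untreated pair), while for the distance of the thinned sums, 1.26 times that of the untreated pair (SD 0.0170 over 20 thinnings), the value lay above the bound against depth by less than 2 SD and depth stays open. A wrong label stays open, since irradiated CD45 knockouts had as little as 1.08% in cluster 24, as does a real difference between the mice, which the design cannot test.

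Fkbp5, Tsc22d3, Klf9 and Ddit4, which glucocorticoids induce in many cells, were among the genes higher in irradiated macrophage-like cells, and glucocorticoid exposure of the mice or cells may be the cause. In macrophage-like cells of GDC-0449 replicate 2, Fkbp5 and Klf9 were also high (135 and 76.2 CPM by total UMIs), against 14.8 and 5.94 CPM in replicate 1. Held-out glucocorticoid-responsive genes, 12 of them tested, had a median log2 fold change of 0.862 in irradiated macrophage-like cells, at percentile 100 of random lists. Of the 12, 2 were called there and 0 in each other comparison. However, Dusp1 had been seen before the list was written, and Il1r2, also on it, is a leading gene of neutrophil-like cluster 1. In microglia-like cells the list was at percentile 100 after GDC-0449 and at 99.9 after radiation. The dissociation stress list, which also holds Dusp1, was higher in microglia-like cells after GDC-0449 too. There it was not set against a bound, so the percentile does not separate the 2 explanations. Fkbp5 in these sums was at 26.0 CPM in GDC-0449 replicate 1 and at 149 CPM in replicate 2, by total UMIs. In macrophage-like cells after GDC-0449 it was at percentile 80.3 (median 0.0747). Neutrophil RNA was the first technical candidate, since the median log2 fold change of 12 neutrophil markers was 1.82. Of these, Camp (-4.11), Ltf (-0.925) and Csf3r (-0.0599) were lower and the rest higher. At the share set by S100a8, neutrophil RNA would bring 94.1% of the rise of Lcn2. It would bring at most 8.10% of the rise of Fkbp5, Tsc22d3, Klf9, Ddit4 or Zbtb16, so it is excluded for these 5, and for Per1 (15.2%) no bound was met. Dissociation stress stays open, as its list had a median of 0.457, between the bounds, and the labels name no steroid.

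Unnamed cluster 5 held 1447 cells, 39.0% of the blood library, and at most 1 cell in any other, with Prg4, Alox15 and Serpinb2 among its leading genes. Peritoneal macrophages in the blood library are a candidate explanation, since 4 of 6 held-out peritoneal genes, Gata6 (90.1 CPM), Tgfb2 (227 CPM), Selp (216 CPM) and Garnl3 (130 CPM), met both bounds written before. Rarb (13.5 CPM) and Cxcl13 (8.13 CPM) did not. Doublets were called 4.49 times as often in this cluster as in the rest of the library (5.84% against 1.30%), which met the bound written before, but a mix of 2 cells cannot exceed its richer parent, and these genes were at least 9.10 times as high as in any other blood cluster. How such cells came into a blood sample was not tested.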

How the results depend on the processing

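The alternatives with 1 round of clusters, with the cycling cluster left out, with named cells as denominator and with shared barcodes left out were chosen after seeing the data, and the others before the data were examined. Of the values of named genes under these alternatives, 1873 kept their direction and their side of the threshold, 512 were no longer called, 168 became called and 10 changed sign. For gene lists these numbers were 355, 19, 0 and 2, and for single class shares 115, 0, 3 and 9. Of the values that answer a comparison 113 stayed as they were, counts within 1.5 times, while 61 were higher, 57 lower, 13 correlations moved and 2 changed sign. Values below are numbers of called genes unless stated. Where edgeR called 0 genes in microglia-like or macrophage-like cells or in their comparison, between 174 and 1995 genes had an unadjusted p under 0.05, and DESeq2 was run with the main settings alone. Where a setting changed a result, the cause was not tested, except that leaving out a replicate or the filter on low counts changes the samples or the genes tested.

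With the DESeq2 Wald test, microglia-like cells gave 154 genes for GDC-0449 against untreated, 345 for radiation against untreated, 290 for radiation against GDC-0449, 35 for Ccr2 knockout against intact in the CD45 libraries, 180 for untreated tumor against cerebellum and 33 for the CD11 knockout. Macrophage-like cells gave 43 for GDC-0449, 12 for radiation against GDC-0449 and 167 for the CD45 knockouts, and the treatment effect by cell class gave 1 for GDC-0449 and 72 for radiation. The overlap of GDC-0449 and radiation effects, monocyte-derived macrophage-like, had a correlation of 0.62.

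With no low-count filter, microglia-like cells gave 664 genes for GDC-0449, 1124 for radiation, 912 for radiation against GDC-0449, 148 for the CD45 knockouts, 566 for tumor against cerebellum and 274 for the CD11 knockout. Macrophage-like cells gave 365, 868, 148, 767 and 242 in the same order without cerebellum, other classes, treatments and Ccr2, 962, and the treatment effect by cell class 101 for GDC-0449 and 341 for radiation. The correlation for the overlap of GDC-0449 and radiation effects, monocyte-derived macrophage-like, was 0.52. With relative log expression size factors the microglia-like cells gave 0 for radiation (edgeR).

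With doublets kept, microglia-like cells gave 1 gene for radiation, macrophage-like cells 1 for GDC-0449, 260 for radiation and 0 for the CD45 knockouts, the other classes 59 and the treatment effect by cell class 2 for GDC-0449, with a correlation for the overlap of GDC-0449 and radiation effects, monocyte-derived macrophage-like, of 0.50. With the strict cell filter, microglia-like cells gave 32 for GDC-0449, 1 for radiation and 85 for radiation against GDC-0449, macrophage-like cells 0 for GDC-0449, 301 for radiation and 77 for the CD45 knockouts, and the treatment effect by cell class 2 for GDC-0449. The correlation for the overlap of GDC-0449 and radiation effects, microglia-like, was then 0.42 and for the macrophage-like 0.49, and 1 class share passed for radiation. The strict filter turned the sign of the interferon response list in macrophage-like cells (GDC-0449, 0.50), of Rsad2 in the treatment effect by cell class (0.96) and of the monocyte-like share without Ccr2 (0.34).

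At Leiden resolution 0.6, microglia-like cells gave 2 genes for GDC-0449, 181 for radiation and 340 for radiation against GDC-0449, macrophage-like cells 1 for GDC-0449 and 16 for the CD11 knockout, and the treatment effect by cell class 0 for GDC-0449 and 334 for radiation. The sign turned for Gadd45b in tumor against cerebellum (0.63), for the microglia-like share after GDC-0449 (-0.41) and for the overlap of GDC-0449 and radiation effects, microglia-like (-0.11). At resolution 1.6, microglia-like cells gave 79 for radiation against GDC-0449, macrophage-like cells 203 for the CD45 knockouts, and the macrophage-like share after GDC-0449 turned its sign (2.51).

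With 1 round of clusters, microglia-like cells gave 38 genes for GDC-0449, 59 for radiation and 309 for radiation against GDC-0449, macrophage-like cells 0 for GDC-0449, 1 for radiation, 0 for the CD45 knockouts and 20 for the CD11 knockout, and the treatment effect by cell class 0 for GDC-0449 and 242 for radiation. The sign turned for Gadd45b in tumor against cerebellum (0.35), for Prnp in the treatment effect by cell class (-0.039), for the microglia-like share after GDC-0449 (-0.45), for the monocyte-like share without Ccr2 (0.075) and for the overlap of GDC-0449 and radiation effects, microglia-like (-0.024), with 0.47 for the monocyte-derived macrophage-like. For radiation 1 class share passed.

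With the cycling cluster left out, microglia-like cells gave 0 genes for GDC-0449, for radiation and for radiation against GDC-0449 (edgeR), the treatment effect by cell class 76 for radiation, and the overlap of GDC-0449 and radiation effects, microglia-like, a correlation of 0.59. In radiation against GDC-0449 the sign turned for Pclaf (-2.24), Mki67 (-0.24), Cenpf (-1.56) and the cell cycle list (-0.24), and without Ccr2 for Top2a (0.083).

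With all groups in 1 fit, microglia-like cells gave 46 genes for GDC-0449, 12 for radiation and 133 for radiation against GDC-0449, and macrophage-like cells 72 for radiation, with correlations of 0.42 and 0.56 for the overlap of GDC-0449 and radiation effects, microglia-like and monocyte-derived macrophage-like. With the irradiated CD45 libraries only, the knockouts gave 23 in microglia-like and 0 in macrophage-like cells. With shared barcodes left out they gave 142 in macrophage-like cells, all 47 among them. With TMM over classes the macrophage-like share without Ccr2 turned its sign (0.34). With an estimated correlation 0 gene lists passed in each comparison.

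With each replicate left out in turn, the group that keeps 1 library is assumed to vary like the other groups. Microglia-like cells then gave 1 to 328 genes for GDC-0449, 0 to 1 for radiation, 0 to 608 for radiation against GDC-0449, 0 for the CD45 knockouts both times, 4 to 105 for tumor against cerebellum and 9 for the CD11 knockout. Macrophage-like cells gave 2 to 224 for GDC-0449, 0 to 140 for radiation, 0 to 20 for radiation against GDC-0449, 2 to 174 for the CD45 knockouts and 8 to 14 for the CD11 knockout. The treatment effect by cell class gave 11 to 176 for GDC-0449 and 156 to 359 for radiation. The correlation was 0.51 to 0.58 for the overlap of GDC-0449 and radiation effects, microglia-like, and 0.54 to 0.83 for the overlap of GDC-0449 and radiation effects, monocyte-derived macrophage-like, and 0 to 1 class shares passed for radiation. The sign of Ttr in the treatment effect by cell class turned without untreated replicate 1 (-1.44) and without GDC-0449 replicate 2 (-2.32), in a range up to 2.39, that of the microglia-like share after GDC-0449 without untreated replicate 2 (-0.15) and without GDC-0449 replicate 1 (-0.87), and that of the log2 fold in cell class shares, treatments, GDC-0449 against untreated, monocyte-derived macrophage-like, without untreated replicate 2 (0.64, in a range down to -3.12).

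With too few cells in a class or no residual degrees of freedom, these were not run: the 3 macrophage-like treatment comparisons and both treatment effects by cell class at Leiden resolution 1.6, the macrophage-like and NK cell-like Ccr2 comparisons at 0.6, the B cell-like one with the strict filter, and the B, NK and T cell-like ones with a replicate left out. Depth limits how many genes pass the filter on low counts, 11143 in microglia-like and 4066 in B cell-like sums of the Ccr2 comparison. In that comparison the median was 1674 UMIs per macrophage-like cell in the intact library against 9222.5 and 6862 in the knockouts, and depth was not tested as a cause. No paired analysis was possible because the replicate numbers pair nothing.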

Other observations

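Of the tests of this part, the one of chance sharing of barcodes was chosen after the count was seen, the one of similarity was written after the count, the UMI ratios and the match of cell classes were seen and before any similarity was computed, and unnamed cluster 33 was looked at after the clusters were seen.

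The barcodes shared by the intact CD45 library and CD45 knockout replicate 2 may hold reads of each library that were assigned to the other. If so, a copy should resemble its namesake more than a random cell of the same class in the library of the namesake, and 99.8% of 541 copies did, with a median cosine similarity of 0.902 against 0.601. Chance sharing is excluded, since the shared barcodes were 16.3 times the number expected. Any other pair of libraries shared at most 32 barcodes. The copies are a part of this pattern, and reads exchanged between cells whose barcodes were called in only 1 of the 2 libraries were not measured.

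Border-associated macrophage-like cells were 18.4% and 0.453% of the irradiated libraries, so the 2 replicates stood apart in this class. Unnamed cluster 33 held 0.772% and 6.81% of the cells of untreated tumor, 1.0% and 1.38% after GDC-0449, none of the irradiated CD11 cells and 0.364% of cerebellum. Monocyte-like cells were 10.8% of GDC-0449 replicate 2, of which cluster 39 held 91.5%.

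Between cerebellum and blood, the remaining lists gave these median log2 ratios, positive where cerebellum was higher. Disease-associated microglia genes were at 1.75 and chemokines at 1.90, both above all 10000 random lists. Lymphocyte activation and checkpoint genes were at 1.43 (percentile 97.98), cell cycle genes at 0.73 (percentile 96.08), complement genes at 0.62 (percentile 96.22), and cholesterol and lipid handling genes at 0.54 (percentile 93.51). MHC class I genes were at -0.59 (percentile 1.0) and MHC class II genes at -0.22 (percentile 24.64). Phagocytosis and scavenging genes were at 0.17 (percentile 48.04) and p53 targets at 0.37 (percentile 25.65). Glycolysis and hypoxia genes were at 0.62 (percentile 90.44), immediate early and dissociation stress genes at 0.28 (percentile 86.0), inflammatory NF-kB genes at 0.30 (percentile 57.3), immune suppression genes at 0.45 (percentile 68.65) and growth and matrix factors at 0.45 (percentile 73.69).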
